A study of Homo sapiens with 6 samples.

How the data were processed

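RNA was measured by sequencing of oligo(dT)-selected libraries from HT1080 cells, an established human fibrosarcoma line. The labels give 6 libraries in 2 groups of 3, named by treatment as RSL3 and LA. RSL3 is a small molecule that inhibits the lipid peroxidase GPX4 and triggers ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. The labels do not expand LA, and it is used here as a group name. All 6 libraries carry the batch label day0 and none is labelled as an untreated control, so each comparison is RSL3 minus LA.

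The processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR, and give GRCm39, a mouse genome build. The deposited table holds 39806 genes with human Ensembl identifiers. Of these, 37597 are also in GENCODE release 29, and 37586 of those overlap their position there on the human build GRCh38, so positions are given on GRCh38. Per the file headers, the authors list counts per gene, which are taken here as estimated counts (not scaled for depth), and FPKM (fragments scaled by transcript length and mapped depth). How many listed counts correspond to 1 sequenced fragment was not settled. Total counts ran from 62184571 to 73449366 per library, and the floor of 3 counts per library corresponds to 0.0370 to 0.0537 CPM (counts scaled to a common library total). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

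Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and groups were compared by the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Levels are CPM on TMM-scaled totals, as mean ± SD with n = 3 per group, and fold changes are given on the log2 scale ± SE. No fold is given for a gene at 0 in all RSL3 libraries, because the floor of 3 counts lies under the estimated 44.4 to 86.2 counts per distinct molecule there. Instead, the distinct molecules expected over the 3 RSL3 libraries at the LA level were estimated, after the data were seen, and with fewer than 3 a zero was taken as not informative. The 33 gene lists were fixed before the data were examined. Of their 758 symbols, 747 matched the table by symbol, 2 by gene identifier, and 9 were not matched. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Shares of the counts were compared by two-sided exact permutation tests, which cannot give a p below 0.1 for 3 libraries against 3.

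The rule for named genes was also fixed before the data were examined. It takes PRKDC, XRCC5, XRCC6, LIG4, XRCC4, NHEJ1, DCLRE1C, GPX4, SLC7A11 and ACSL4 whatever their values. It adds the 8 highest and 8 lowest fold changes among genes with a symbol that passed the test, had a mean log2 CPM of at least 3 and showed no overlap between groups. From each shifted list it takes up to 4 members that passed with the smallest adjusted p, and from each other list up to 2. The rule gave 102 genes, and any other gene named was chosen after its values were seen. Of these, 1 gene is not reported here, nor is 1 of the 33 lists. The test was checked on simulated counts with 3 libraries per group.

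Alternatives chosen before the data were examined were RLE size factors, total count scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a replicate block, each library left out in turn, DESeq2 1.42.0, limma-voom, and limma on log2 FPKM with a pseudocount of 1 or 0.1. For the lists they were an estimated correlation and fry. Alternatives added after the data were seen were offsets for transcript length and GC content, leaving out mitochondrially encoded genes, counts divided by 4, and a filter on a mean of at least 8 CPM. The offsets came from splines with 5 degrees of freedom per library on lengths from GENCODE 29. Length was first the median over basic transcripts, and the principal transcript by APPRIS was added after the results with the median had been seen. Gene Ontology terms of 10 to 200 tested genes, as the deposited table pairs them with genes, were also tested by camera after the data were seen. Shares, permutation tests and library measures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. No value column of the table was left unmapped.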

Results

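Gene expression was measured in HT1080 cells in 3 RSL3 libraries and 3 LA libraries. Total counts were 62738057, 62184571 and 65966524 in RSL3 replicates 1 to 3, and 64856810, 70007291 and 73449366 in LA replicates 1 to 3. The groups' totals did not separate beyond the spread between replicates (exact permutation p = 0.2). Mitochondrially encoded genes took 13.8% ± 0.540 (SD, n = 3) of the counts in RSL3 and 2.64% ± 0.0335 (n = 3) in LA. Ribosomal protein genes took 9.72% ± 0.153 in RSL3 and 4.29% ± 0.0304 in LA. The number of genes with any count was 17556, 19968 and 20885 in the RSL3 libraries and 28273, 28479 and 28595 in the LA libraries. For these 3 measures the 3 libraries of each group lay apart from the other group's, with an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give.

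**Figure D1:**
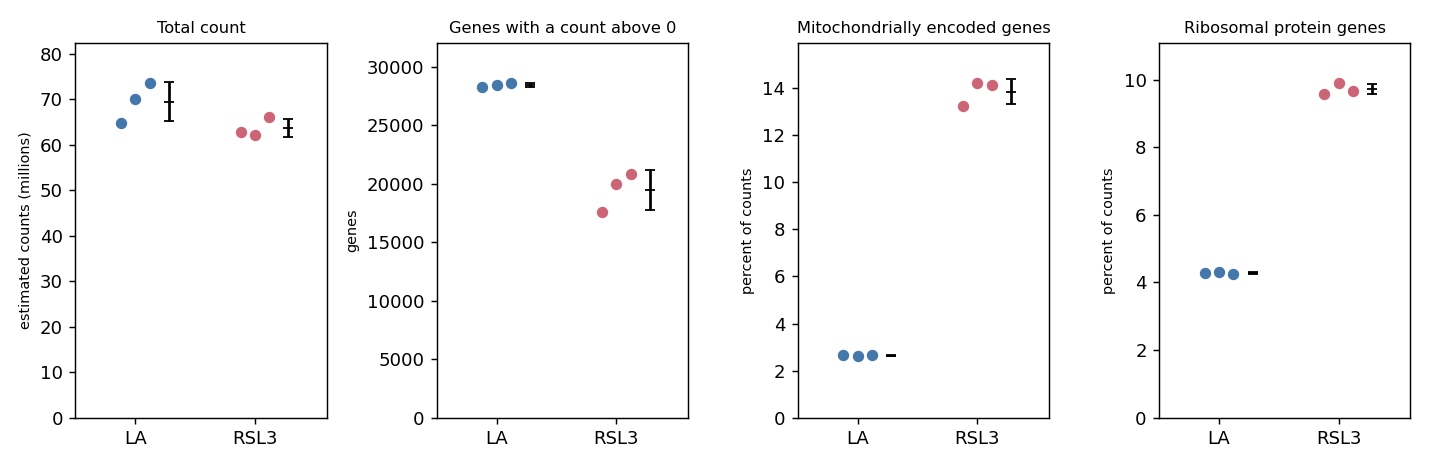
Total estimated counts per library, genes with a count above 0, and the percent of counts from mitochondrially encoded and from ribosomal protein genes, with 1 point per library and bars for mean ± SD (n = 3). The RSL3 libraries have 17556 to 20885 genes above 0 against 28273 to 28595 in LA, and larger mitochondrial and ribosomal protein shares.

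The series is titled around DNA-PKcs-dependent end joining and the inhibition of ferroptosis, and the comparison asks how transcript levels differ between cells labelled RSL3 and cells labelled LA. PRKDC, which encodes the DNA-PK catalytic subunit DNA-PKcs, fell from 683 ± 20.5 CPM in LA to 209 ± 9.61 CPM in RSL3 (n = 3 each), a 3.27-fold lower level. SLC7A11, the cystine importer subunit that supplies glutathione synthesis, fell 2.28-fold, and GPX4, the lipid peroxidase that RSL3 inhibits, rose 1.75-fold. Mitochondrially encoded, ribosomal protein, heat shock, S phase, oxidative phosphorylation, glycolysis and cholesterol synthesis transcripts were higher in RSL3 as groups, and ATF4 target transcripts were lower. With an estimated correlation 0 of these 8 lists passed (camera adjusted p from 0.0782 to 0.198). Of 20605 genes tested, 2877 were higher and 4267 lower in RSL3 at an edgeR adjusted p under 0.05. Of the lower genes, 1102 were at 0 in all RSL3 libraries. For 903 of these fewer than 3 distinct molecules would be expected over the RSL3 libraries at the LA level, so that their zeros do not show a fall.

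PRKDC (ENSG00000253729, chromosome 8, 47773111 to 47960178, minus strand) had a log2 fold change of -1.71 ± 0.05 (edgeR adjusted p = 2.74e-06). With offsets for transcript length and GC content it was -1.22 with the median transcript and -1.23 with the principal one. Its partners in DNA-PK, the DNA end-binding Ku subunits, moved less. XRCC6, which encodes Ku70, rose from 388 ± 3.94 to 483 ± 11.04 CPM (log2 0.32 ± 0.03, edgeR adjusted p = 0.000714), though not under each alternative. The call ended with total count scaling (log2 0.04, adjusted p = 0.379) and on the FPKM values it passed as lower (-0.15 with a pseudocount of 1 or 0.1, adjusted p = 0.00477 and 0.00445). These settings lower genes as a whole. The median of all genes moved by -0.28 with total count scaling, and by -0.13 and -0.46 on FPKM with a pseudocount of 1 and 0.1. A pseudocount of 1 pulls genes with low values toward no change, so -0.13 understates the shift of well expressed genes such as XRCC6. Calls as lower under these settings therefore do not show a fall particular to a gene. XRCC5, which encodes Ku80, was at 362 ± 26.2 CPM in RSL3 and 405 ± 2.70 in LA and did not pass (edgeR adjusted p = 0.0700). It passed as lower with total count scaling (log2 -0.44, adjusted p = 0.000758), without RSL3 replicate 3 (-0.21, adjusted p = 0.0243), by limma-voom (-0.16, adjusted p = 0.0340) and on log2 FPKM with a pseudocount of 1 (-0.62) and 0.1 (-0.63), and was at 0.02 with the median transcript offsets. The ligase LIG4 (54.1 ± 5.12 against 51.1 ± 1.63 CPM), its partner XRCC4 (19.7 ± 5.14 against 15.2 ± 0.816), the ligation factor NHEJ1 (17.4 ± 3.93 against 13.9 ± 0.786) and the nuclease DCLRE1C (17.8 ± 2.99 against 14.7 ± 1.15) did not pass, with edgeR adjusted p values from 0.215 to 0.541. On the FPKM values LIG4 passed as lower (log2 -0.34 and -0.38 with a pseudocount of 1 and 0.1). SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349) went from 576 ± 15.6 CPM in LA to 252 ± 19.6 in RSL3 (log2 -1.19 ± 0.06, edgeR adjusted p = 3.36e-05). GPX4 (ENSG00000167468, chromosome 19, 1103994 to 1106779) went from 67.6 ± 0.990 to 118 ± 19.4 CPM (log2 0.81 ± 0.12, edgeR adjusted p = 0.00289), and was at 0.53 with total count scaling and did not pass on log2 FPKM with a pseudocount of 0.1 (0.32). ACSL4, which loads polyunsaturated fatty acids into membrane lipids, went from 122 ± 5.96 to 103 ± 4.66 CPM (log2 -0.24 ± 0.06, edgeR adjusted p = 0.0202). Its call ended without LA replicate 1 (log2 -0.27), without LA replicate 3 (-0.21), without RSL3 replicate 2 (-0.21), at a mean of at least 8 CPM (-0.16), and with the length and GC offsets (-0.01 and -0.08).

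**Figure D2:**
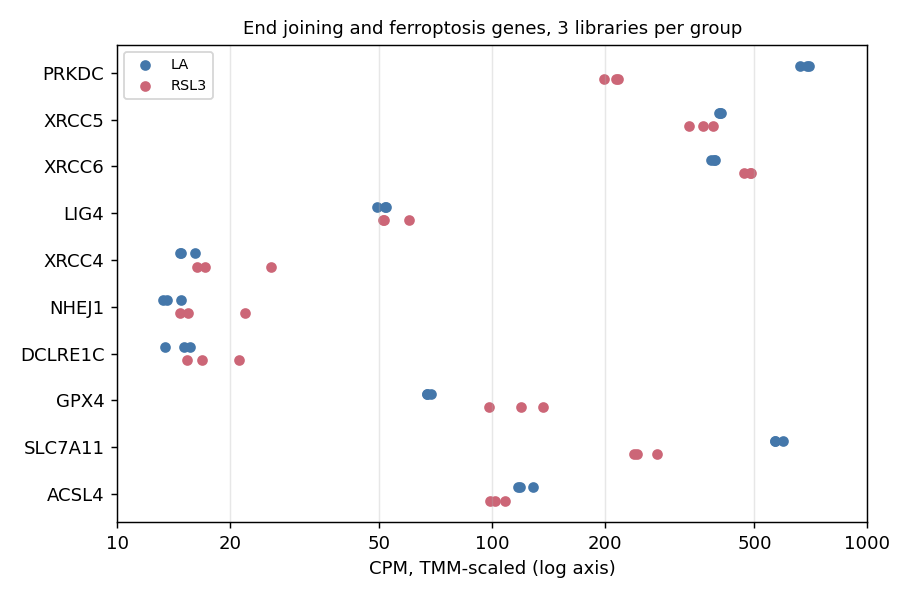
CPM on TMM-scaled totals (log axis) of 10 end joining and ferroptosis genes, with 1 point per library, 3 per group. The 3 RSL3 libraries lie below the 3 LA libraries for PRKDC, SLC7A11, ACSL4 and XRCC5, and above them for GPX4, XRCC6 and XRCC4. XRCC5 and XRCC4 did not pass the edgeR test.

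As groups, the DNA repair lists did not move with PRKDC. Of 20 tested members of the non-homologous end joining list, 2 rose (XRCC6 and MAD2L2), 5 fell and 13 did not pass, and the list was not shifted (camera adjusted p = 0.827). With PRKDC, TP53BP1, which promotes end joining (log2 -0.77, edgeR adjusted p = 0.000589, or -0.38 and -0.40 with the median and principal transcript offsets), POLM and POLL were among those that fell. In the homologous recombination list 9 of 30 rose and 5 fell (camera adjusted p = 0.328), among them RMI1 (log2 0.68) and the single-strand binding subunit RPA2 (0.81, or 0.53 with the median transcript offsets), which rose but did not pass on the FPKM values (0.21 and 0.33 with a pseudocount of 0.1). The 5 that fell were RAD50, MRE11 and NBN, which form 1 complex, with RAD52 and RAD51D. In the base excision and single-strand break repair list 3 of 24 rose and 2 fell (camera adjusted p = 0.183, or 0.0409 with no low-count filter), and the replication clamp PCNA (log2 1.40), the flap nuclease FEN1 (0.72) and UNG were those that rose. POLD1 and LIG3 fell. The DNA damage signalling list was shifted upward, with 9 of 20 higher and 3 lower (9 and 4 adjusted over the list alone) and a median log2 fold change of 0.24 (camera adjusted p = 0.0434). This call was lost with total count scaling (adjusted p = 0.0579), where the median turned to -0.04, and with an estimated correlation (0.198). It was also lost without RSL3 replicate 1 (0.0705, median 0.31), with a replicate block (0.0508, 0.21), at 1 CPM in 3 libraries (0.113, 0.29), with counts divided by 4 (0.102, 0.27) and at a mean of at least 8 CPM (0.175, 0.52). In these the median stayed positive. With the length and GC offsets the median was higher, at 0.46 and 0.45, and the list was shifted (adjusted p = 0.00408 and 0.00286). RNF168 (log2 1.11) and the checkpoint mediator CLSPN (1.81) were among those that rose, whereas TIMELESS, TOPBP1 and the kinase ATM fell (ATM -1.06, or -1.94 and -0.66 with the median and principal transcript offsets). For ATM the median length is 587 nt and the principal one 13147 nt, so the median offsets treat it as a short transcript.

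The ferroptosis lists were not shifted in either direction. Of 21 defence genes 5 rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.872), with the ferritin light chain FTL (log2 0.77, or 0.37 and 0.33 with the length and GC offsets), PRDX6, CISD1, DHCR7 and GPX4 higher and the thioredoxin reductase TXNRD1 lower (-0.70). Of 21 promoting genes 6 rose and 8 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.827), and the heme oxygenase HMOX1 (log2 0.57) and the channel VDAC3 (1.002, or 0.46 and 0.64 with the offsets) were among those that rose. HMOX1 did not pass on the FPKM values (0.11). Of 14 transcript markers of ferroptosis 3 rose and 8 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.213), and ATF3, HMOX1 and RGS4 were those that rose. NRF2 targets split into 9 higher and 8 lower of 30 (11 and 8 adjusted over the list alone, camera adjusted p = 0.233), and thioredoxin TXN rose (log2 1.45, or 0.72 and 0.79 with the offsets). ATF4 and integrated stress response genes were lower as a group: 27 of 32 fell and 2 rose (29 and 2 adjusted over the list alone), with a median log2 fold change of -0.62 (camera adjusted p = 2.59e-05, or 0.0782 with an estimated correlation). With the length and GC offsets the median was -0.35 and -0.41, and the list stayed shifted. TRIB3 fell from 373 ± 2.33 to 108 ± 2.57 CPM (log2 -1.80), SESN2 fell (-1.33) and the tryptophanyl-tRNA synthetase WARS1 fell (-0.92), whereas ATF3 (0.77) and STC2 rose. Endoplasmic reticulum chaperones and unfolded protein response genes split into 7 higher and 9 lower of 22 (8 and 10 adjusted over the list alone, camera adjusted p = 0.977), with HYOU1 (log2 -0.93, or -0.61 and -0.54 with the offsets) and HSPA5 (-0.79) lower. The heat shock response rose as a group, with 16 of 20 higher and 0 lower, and a median log2 fold change of 0.84 (camera adjusted p = 6.02e-11, or 0.0782 with an estimated correlation). HSPA8 rose from 496 ± 9.997 to 2369 ± 33.9 CPM (log2 2.26) and the mitochondrial co-chaperonin HSPE1 rose (3.01). HSPA1A (3.77) and HSPA1B (3.62) also rose, but share reads with each other.

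All 13 mitochondrially encoded protein transcripts rose, with a median log2 fold change of 2.71 (camera adjusted p = 7.1e-15, or 0.198 with an estimated correlation). MT-CO3, a cytochrome oxidase subunit, went from 1738 ± 4.09 to 21411 ± 1583 CPM (log2 3.62), and MT-ATP6 (3.54), MT-CYB (2.95) and MT-ND3 (5.35) rose with it. Of 30 nuclear-encoded oxidative phosphorylation genes 19 rose and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 1.18e-09, or 0.0782 with an estimated correlation). UQCRB (log2 2.25, or 1.42 with the median transcript offsets), NDUFA4 (1.82), COX7C (1.69, or 0.91) and NDUFA1 (2.63), all subunits of respiratory complexes, were among those that rose, and NDUFS1 fell. Of 31 cytosolic ribosomal protein genes 30 rose and 0 fell, with a median log2 fold change of 1.34 (camera adjusted p = 1.14e-23, or 0.13 with an estimated correlation). RPS23 went from 303 ± 8.56 to 1686 ± 34.4 CPM (log2 2.47), and RPL37 (2.61), RPL27 (2.14, or 1.38 with the median transcript offsets) and RPL32 (1.898) rose as well. These genes have short transcripts, and across genes the fold change fell with transcript length: its median was 1.55 for principal transcripts up to 500 nt and -0.35 for those over 8000 nt. Genes are not independent replicates. With the length and GC offsets the medians were 2.46 and 2.36 for the mitochondrially encoded list, 0.37 and 0.38 for oxidative phosphorylation (0.40 with total count scaling), and 0.95 and 1.05 for ribosomal proteins, and these 3 lists stayed shifted. Of the 13 mitochondrially encoded transcripts 12 rose and 1 fell with the median transcript offsets.

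**Figure D3:**
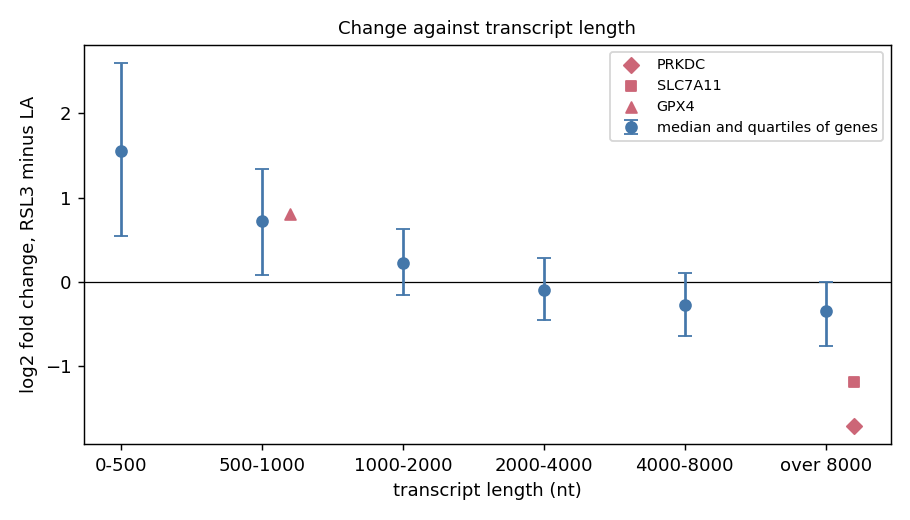
Median log2 fold change (RSL3 minus LA, vertical axis) of genes with a mean log2 CPM of at least 3 in bins of principal transcript length in nt (horizontal axis), with bars from the lower to the upper quartile and separate points for PRKDC, SLC7A11 and GPX4. The median goes from 1.55 in the shortest bin to -0.35 in the longest, and PRKDC lies at -1.71.

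Replication transcripts were higher in RSL3 as a group. In the S phase and DNA replication list 22 of 30 rose and 2 fell, with a median log2 fold change of 0.60 (camera adjusted p = 1.33e-08, or 0.0848 with an estimated correlation), and a median of 0.32 with total count scaling. The cyclin CCNE2 rose from 3.67 ± 0.463 to 24.4 ± 5.20 CPM (log2 2.73), and thymidylate synthase TYMS (1.21) and the replicative helicase factor GINS2 (1.43) rose, whereas POLA1 and MCM7 fell. G2 and mitosis genes split into 8 higher and 10 lower of 30 (camera adjusted p = 0.916), with UBE2C higher (log2 0.98, or 0.37 and 0.45 with the offsets) and the spindle factor TPX2 lower (-0.82). The ubiquitin ligase MDM2 rose (log2 0.94, or 0.34 and 0.91 with the length and GC offsets, where its median length is 891 nt and its principal one 2523 nt). Of 14 replication-dependent histone genes 1 rose and 3 fell (camera adjusted p = 0.736). H2AC6 (log2 -1.11), H2AC8 and H1-4 were lower, and H2BC12 was higher (0.51) but turned to -0.19 and -0.14 with the offsets. Its call was also lost without LA replicate 1, 2 or 3 (adjusted p = 0.0649, 0.0612 and 0.0548), with total count scaling (log2 0.24) and on the FPKM values (0.04).

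Cholesterol synthesis and glycolysis transcripts were higher in RSL3. In the cholesterol synthesis and SREBP2 list 15 of 25 rose and 2 fell, with a median log2 fold change of 0.55 (camera adjusted p = 5.67e-05, or 0.0782 with an estimated correlation), and a median of 0.27 with total count scaling. IDI1 went from 60.6 ± 2.83 to 229 ± 14.4 CPM (log2 1.92), and ACAT2 (1.32), HMGCS1 (0.94) and MSMO1 (1.07) rose, whereas STARD4 and SREBF2, which encodes the transcription factor SREBP2, fell. In the hypoxia and glycolysis list 18 of 28 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 6.88e-08, or 0.198 with an estimated correlation), or 0.31 with total count scaling. The lactate dehydrogenase LDHA (log2 1.21), GAPDH (0.81), ENO1 (0.57) and the mitophagy receptor BNIP3 (1.54) rose, and VEGFA fell. Fatty acid synthesis and desaturation genes were not shifted, with 1 of 22 higher and 9 lower (1 and 10 adjusted over the list alone, camera adjusted p = 0.165), except with total count scaling, where the list was shifted downward (median -0.47, camera adjusted p = 0.0375). ELOVL5 was higher, SREBF1 fell (log2 -1.73, or -0.97 and -1.01 with the offsets), and fatty acid synthase FASN fell (-0.93) but was at 0.05 and 0.04 with the length and GC offsets. Of 25 PPAR targets and fatty acid oxidation genes 5 rose and 3 fell (camera adjusted p = 0.415), with ACADM (log2 0.58), ECI2 (0.44), ETFA, ETFB and EHHADH higher and ACADVL, ACADL and HADHB lower. ACADM did not pass on the FPKM values (0.10 and 0.12). ECI2 turned to -0.02 and -0.03 on the FPKM values and did not pass with total count scaling (0.17) or the offsets (0.21 and 0.20). Of 7 tested genes of the metallothionein list 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.354), and MT2A (log2 0.76, or 0.26 and 0.50 with the offsets) and MT1X (1.39, or 0.61 and 0.54) rose while the zinc exporter SLC30A1 fell.

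Signalling, cell death and matrix lists held changes in both directions and were not shifted. Of 30 immediate early genes 8 rose and 12 fell (camera adjusted p = 0.697): FOSB went from 2.52 ± 0.410 to 58.4 ± 5.75 CPM (log2 4.54) and the phosphatase DUSP5 fell (-1.67). Of 22 NF-kappaB and inflammatory cytokine genes 4 rose and 6 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.827), with NFKBIZ (log2 -2.01) and LIF (-0.60, or -0.34 and -0.23 with the offsets) lower and IL1B, IL11, CXCL8 and NFKBIA higher. Of 28 type I interferon response genes 2 rose and 5 fell (camera adjusted p = 0.827), with ISG15 and IFIT2 higher, IFI35 (log2 -0.66), STAT2 and OAS3 among those lower, and BST2 at 0 in all RSL3 libraries and 4.17 ± 0.201 CPM in LA, where an unchanged level would give an estimated 13.001 distinct molecules over the RSL3 libraries. Of 30 lysosome and autophagy genes 4 rose and 13 fell (4 and 15 adjusted over the list alone, camera adjusted p = 0.529), where the autophagy receptor NBR1 rose (log2 2.19) with NEU1, GLA and GABARAPL1, and MAP1LC3B fell (-0.88). Of 29 apoptosis, necroptosis and pyroptosis genes 7 rose and 9 fell (7 and 10 adjusted over the list alone, camera adjusted p = 0.977), and the survival factor BCL2L1 (log2 -1.09) and the death receptor TNFRSF10B (-0.64, or -0.41 and -0.38 with the offsets) were lower. Of 29 extracellular matrix and mesenchymal genes 6 rose and 12 fell (6 and 14 adjusted over the list alone, camera adjusted p = 0.355), with the collagen COL6A3 falling from 1227 ± 41.7 to 379 ± 13.6 CPM (log2 -1.69, or -1.11 with either offset) and fibronectin FN1 from 442 ± 6.01 to 154 ± 6.84 CPM (-1.52).

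Transcripts known as markers of other cell types were compared last. Endothelial markers were shifted downward, with 4 of 7 lower and 0 higher and a median log2 fold change of -1.97 (camera adjusted p = 0.0105, or 0.176 with an estimated correlation), a call lost without RSL3 replicate 3 (adjusted p = 0.0525). TIE1 went from 158 ± 3.33 to 48.1 ± 9.95 CPM (log2 -1.71) and ROBO4 from 114 ± 4.20 to 29 ± 7.77 CPM (-1.97). EMCN and VWF were at 0 in all RSL3 libraries, where an unchanged level would give an estimated 1.27 and 0.983 distinct molecules. A fall was therefore not detectable at this depth. Both count among the 4 lower and enter the camera call, which was not repeated with these genes alone left out. With counts divided by 4 the list had too few tested members and was not tested. Neither passed with a replicate block (adjusted p = 0.226 and 0.274), and VWF did not pass on log2 FPKM with a pseudocount of 1 (0.165). With these genes taken as unchanged the list's median was -1.12. Of 10 blood and immune cell markers 4 fell and 0 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.34), with a median of -1.04, or 0.02 with the 4 genes at 0 in RSL3 taken as unchanged. These were CD3E (3.55 ± 0.613 CPM in LA), PTPRC (3.10 ± 0.548), CD8A and LYZ. Unchanged levels of CD3E and PTPRC would give an estimated 11.05 and 9.67 distinct molecules over the RSL3 libraries. For CD8A and LYZ this estimate is not given here, so whether their zeros show a fall is left open. Of 5 hepatocyte and neuronal markers 1 fell (camera adjusted p = 0.415), RBFOX3, at 0.429 ± 0.0945 CPM in LA and at 0 in RSL3, where an unchanged level would give an estimated 1.34 distinct molecules. It did not pass with a replicate block (adjusted p = 0.217) or on log2 FPKM with a pseudocount of 1 (0.0776). Of 8 epithelial markers 2 rose and 0 fell (camera adjusted p = 0.6), KRT7 (log2 1.09) and KRT18 (0.30, which was at 0.02 and did not pass with total count scaling, and passed as lower on the FPKM values, at -0.16 and -0.17). The RSL3 libraries in which these transcripts were at 0 also had fewer genes with any count.

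**Figure D4:**
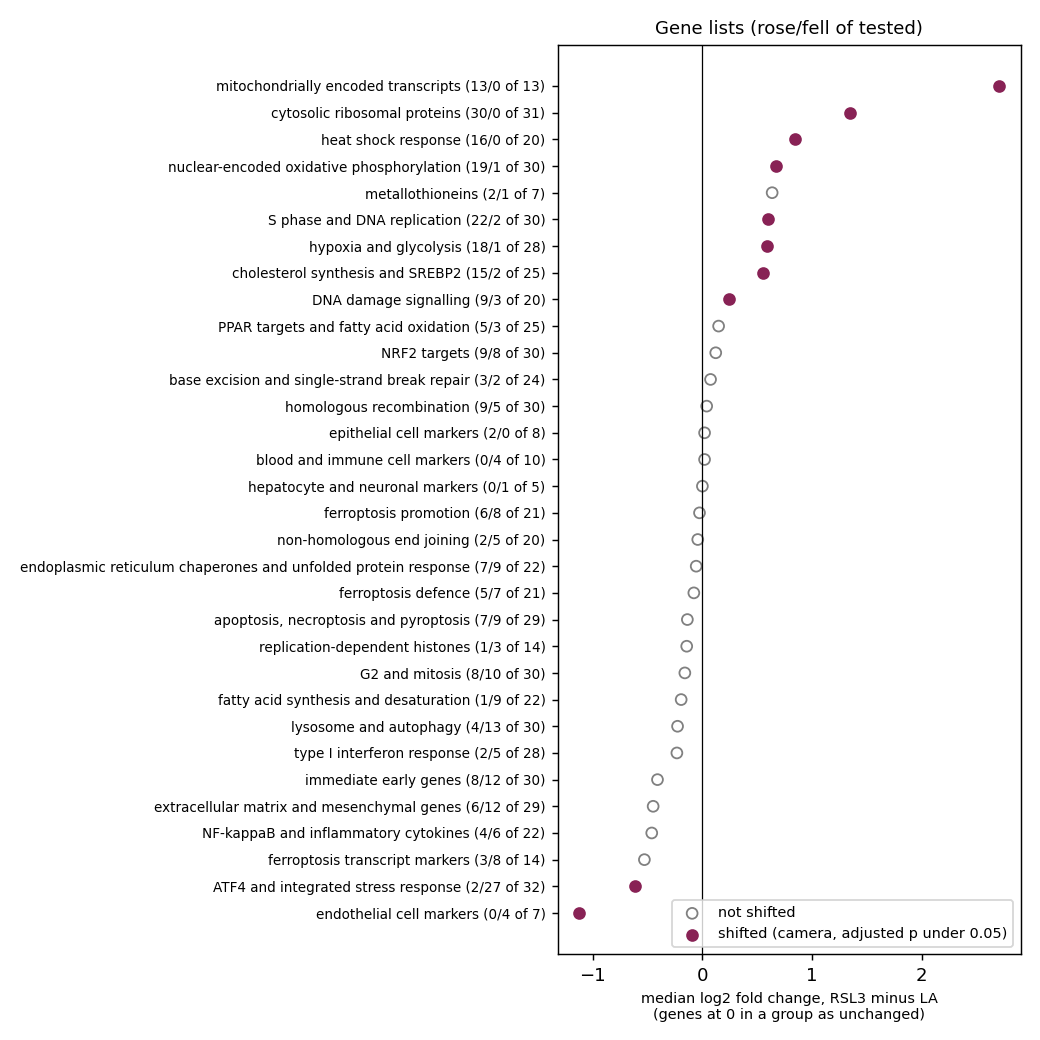
Median log2 fold change (RSL3 minus LA) of the tested members of 32 of the 33 gene lists, with members at 0 in a group taken as unchanged, and the numbers that rose and fell of those tested beside each name. Filled points are the 10 lists shifted by camera, 8 upward and 2 downward, none of which passed with an estimated correlation.

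Among the 8 largest increases, RAB13 (ENSG00000143545, chromosome 1, 153981617 to 153986358), a small GTPase of membrane trafficking, rose from 122 ± 2.35 to 2708 ± 261 CPM (log2 4.48 ± 0.08, edgeR adjusted p = 5.47e-07). The NF-kappaB-inducing kinase MAP3K14 rose from 14.8 ± 0.383 to 294 ± 50.02 CPM (log2 4.31) and the inducible chaperone HSPA6 from 1.35 ± 0.318 to 21.5 ± 5.09 CPM (3.99). MT-ND3, HSPA1A and FOSB belong to lists described with their groups. MT-TS1 (log2 3.68, or 2.35 with the median transcript offsets), a gene of 69 nt annotated as a mitochondrial transfer RNA, also rose. Whether its counts come from the transfer RNA or from other mitochondrial transcripts was not tested. MTATP6P1 (4.03), a nuclear pseudogene of mitochondrial sequence that shares reads with MT-ATP6, completes this group. Among the 8 largest decreases, the granule protease GZMB was at 20.4 ± 1.81 CPM in LA and at 0 in all RSL3 libraries, where an unchanged level would give an estimated 63.5 distinct molecules. The matrix genes TNC (575 ± 15.7 to 88.7 ± 8.33 CPM, log2 -2.70), COL1A1 (35.9 ± 13.2 to 3.22 ± 3.08 CPM, -3.48) and ADAMTS16 (-2.53) fell. LRP11 (log2 -5.26 ± 0.76), the receptor CMKLR2 (-3.29), the glycosyltransferase B3GALT5 (-2.84) and CLIP4 (-2.54) also fell. LRP11 had 9, 123 and 54 counts in RSL3 replicates 1 to 3, and COL1A1 had 392, 104 and 63. ADAMTS16 had 218, 117 and 170 there, and CMKLR2 205, 161 and 171. These are few distinct molecules at the estimated 44.4 to 86.2 counts per molecule, so the sizes of these falls are uncertain. The SE of the COL1A1 change was 0.72.

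In all, 7144 of 20605 genes passed the edgeR test, 3053 of them with an absolute log2 fold change of at least 1 (1112 higher and 1941 lower). Among the lower genes are the 1102 at 0 in all RSL3 libraries, which can pass this fold by their zeros alone. For 903 of them the zeros do not show a fall. These counts therefore do not show that large decreases outnumber large increases. The 3 libraries of each group did not overlap for 53.2% of the tested genes, against 10% given by chance. Genes at 0 in all RSL3 libraries can add to this share in the same way. Total count scaling lowered the median over all genes by a further 0.28 on the log2 scale, and 1787 genes were then higher and 6339 lower. The counts adjusted over the list alone were the same as over all genes in 16 of the 33 lists. In 7 lists that were not shifted the median, the mean and camera's direction differed in sign. Among them, non-homologous end joining, ferroptosis defence, ferroptosis promotion, and G2 and mitosis had negative medians and means with an upward direction, and PPAR targets (median 0.15, mean -0.40) and epithelial markers (0.02, -0.48) had medians and means of opposite sign. With no untreated control, a difference can lie in either group.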

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

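The tests with length and GC offsets, total count scaling, mitochondrial genes left out, pseudogenes, distinct molecules and the floor were chosen after the results they bear on were seen, and the test by thinning before.

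The FPKM columns hold a difference between groups that the count columns do not show. The mapped depth that they imply, divided by the listed total count, was 1.14 times as high in RSL3 as in LA (1.14 ± 0.00744 against 1.0002 ± 0.000774, n = 3, exact permutation p = 0.1, the smallest possible). This lowers the FPKM values of RSL3 relative to its counts, so it is part of the shift of all genes on FPKM.

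PRKDC was lower in RSL3, as many long transcripts were: 384 other genes with principal transcripts of 10000 to 17000 nt had a median log2 fold change of -0.32 (SD 0.65), and 9 of them lay below PRKDC. Transcript length and GC content do not account for it as the whole cause, since PRKDC stayed lower at -1.22 with offsets from the median transcript and -1.23 with those from the principal transcript. A few genes taking most of the counts would lower every other gene alike, by -0.23 for the 76 genes in the top 50 of any library, while PRKDC was at -1.98 ± 0.05 with total count scaling. Leaving out the mitochondrially encoded genes, the test tried first, gave -1.69, which decides nothing, because TMM already absorbs such a shift. A response to the treatments stays open as a hypothesis, as does any difference in RNA quality between the groups, which the labels do not describe.

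Ribosomal protein transcripts were higher in RSL3. Length and GC content do not account for all of the shift, since the list's median stayed at 0.95 and 1.05 with offsets from the median and the principal transcript. The principal length is large for some members, as for RPL37 (7686 nt, median 637 nt) and RPS23 (3437 nt, median 927.5 nt). The principal offsets therefore treat such members as long transcripts. A larger mitochondrial share would lower all other genes by -0.18, whereas the list's median was 1.07 with total count scaling (1.36 without mitochondrially encoded genes, tried first, which decides nothing). The 173 tested ribosomal protein pseudogenes had a median log2 fold change of 1.84, with 84 higher and 4 lower, which decides nothing about shared reads, since these make pseudogenes follow their genes. A biological difference between the treatments and a difference in RNA quality both stay open.

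Fewer genes had any count in RSL3 than in LA. A difference in depth is argued against as the whole cause, since LA libraries thinned to the smallest RSL3 total outside the mitochondrial genome kept at least 28018 genes above 0, and the highest RSL3 library had 20848. The thinning drew each count independently, although several counts can come from 1 distinct molecule, so it can understate the genes lost. A floor that set low RSL3 counts to 0 does not account for it as the whole cause: to bring LA libraries down to the highest RSL3 library it would have to remove counts up to 9, yet each RSL3 library held at least 1054 genes with 1 to 9 counts (6642 to 6804 in LA). The smallest FPKM above 0, tried first, was the same in 5 of the 6 libraries and decides nothing. Fewer distinct molecules behind the RSL3 counts may account for it: estimated from zeros against the other libraries of a group, the counts per distinct molecule were 86.2, 50.6 and 44.4 in RSL3 and 10.8, 11.8 and 11.2 in LA, and the lowest RSL3 value was 3.76 times the highest LA value. This estimate rests on zeros, the pattern to be explained. It cannot tell fewer molecules from a larger spread between replicates, whose chi-square per degree of freedom was 12.3 to 22.6 in RSL3 and 2.75 to 7.34 in LA. The molecules expected for genes at 0 carry the same limit. Of genes with 64 to 256 counts in the other libraries of the group, 25.8% (exact 95% interval 24.3 to 27.4), 13.3% (12.1 to 14.5) and 9.28% (8.27 to 10.4) were at 0 in the RSL3 libraries, against 0.407% to 0.435% in LA; whether the cells held less RNA or the libraries captured less of it was not tested.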

How the results depend on the processing

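The alternatives with length and GC offsets, without mitochondrial genes, with counts divided by 4 and at a mean of at least 8 CPM were chosen after the data were seen, and the principal transcript after the results with the median transcript. PRKDC, SLC7A11 and the medians of the 10 shifted lists, other than DNA damage signalling with total count scaling, kept their direction under each alternative in which they were run, with the log2 fold change of PRKDC from -2.16 to -1.22 and the log2 fold change of SLC7A11 from -1.66 to -0.88. The number of changed genes ran from 5478 to 9642 with 1 library left out, and was 9202 by DESeq2 and 8278 by limma-voom. With total count scaling 1787 genes were higher. On log2 FPKM with a pseudocount of 1, 10754 genes changed, 1475 higher and 9279 lower, and with 0.1, 1459 were higher and 8950 lower. At a mean of at least 8 CPM, where fewer genes are tested (10695), 2820 were lower, and at an absolute log2 fold change of at least 1, 3053 genes passed, 1112 higher and 1941 lower. Genes at 0 in all RSL3 libraries can pass this fold filter by their zeros alone. The share of changed genes that were higher, 40.3%, was 22.0% with total count scaling, 50.6% at 1 CPM in 3 libraries, 50.8% and 52.6% with the median and principal transcript offsets and 51.8% at a mean of 8 CPM. Of 90 named genes that passed and were not at 0 in a group, the log2 fold change moved by over 1.5 times in 17 with total count scaling, 45 and 40 on FPKM with a pseudocount of 1 and 0.1, and 23 and 17 with the median and principal offsets. List medians that shrank by over 1.5 times and kept their call were those of S phase, cholesterol synthesis, glycolysis and oxidative phosphorylation with total count scaling, and of ATF4 targets and oxidative phosphorylation with the offsets. Of the 33 lists, camera with an estimated correlation shifted 0 (7 at an unadjusted p under 0.05) and fry, which asks a different question, 29. With the estimated correlation, calls were lost also in lists where it lay under the preset 0.01, such as ATF4 targets (7.31e-05). Other settings shifted 8 to 11. The DNA damage signalling call was lost with total count scaling (adjusted p = 0.0579, median -0.04), at 1 CPM (0.113), with counts divided by 4 (0.102), at a mean of 8 CPM (0.175) and without RSL3 replicate 1 (0.0705), within a range of 0.00286 to 0.198 over the camera alternatives. Named genes turned with total count scaling (LIG4 -0.19, DCLRE1C -0.0061), on FPKM with a pseudocount of 1 (XRCC6 -0.15, LIG4 -0.34, XRCC4 -0.10, NHEJ1 -0.090, DCLRE1C -0.094, ECI2 -0.023, KRT18 -0.16) and 0.1 (XRCC6 -0.15, LIG4 -0.38, XRCC4 -0.12, NHEJ1 -0.15, DCLRE1C -0.18, ECI2 -0.026, KRT18 -0.17), with median transcript offsets (XRCC5 0.024, H2BC12 -0.19, FASN 0.054) and with principal ones (XRCC4 -0.0015, H2BC12 -0.14, FASN 0.042). Lists that turned in camera's direction were not shifted under that setting, fry apart, and their medians were as follows. With RLE they were endoplasmic reticulum chaperones (-0.014) and apoptosis (-0.093). With total count scaling they were ferroptosis defence (-0.36), ferroptosis promotion (-0.38), end joining (-0.32) and G2 and mitosis (-0.44). With no low-count filter they were endoplasmic reticulum chaperones (-0.071), apoptosis (-0.15) and epithelial markers (-2.09). At 1 CPM in 3 libraries they were ferroptosis defence (-0.029), end joining (0.0080) and G2 and mitosis (-0.11). With the median transcript offsets they were endoplasmic reticulum chaperones (-0.11), immediate early genes (-0.0029), lysosome (-0.051), apoptosis (-0.12) and extracellular matrix (0.0093), and with the principal ones endoplasmic reticulum chaperones (0.025), immediate early genes (-0.032), lysosome (0.044) and apoptosis (-0.029). Without mitochondrial genes endoplasmic reticulum chaperones turned (-0.041), with counts divided by 4 ferroptosis defence (-0.048) and G2 and mitosis (-0.13), and at a mean of 8 CPM end joining (-0.085) and G2 and mitosis (-0.083). In fry, ferroptosis defence (-0.078), ferroptosis promotion (-0.10), end joining (-0.042), G2 and mitosis (-0.16), PPAR targets (0.15) and 1 other list (-0.053) turned, and ferroptosis defence (adjusted p = 0.00289), end joining (0.00043) and the other list (0.0447) passed. With 1 library left out, medians ran from -0.081 to -0.050 for endoplasmic reticulum chaperones, -0.20 to -0.11 for apoptosis, -0.48 to -0.36 for NF-kappaB genes and -1.49 to 0.12 for epithelial markers. With total count scaling the median of all genes moved by -0.28, and on FPKM by -0.13 and -0.46 with a pseudocount of 1 and 0.1. The larger pseudocount pulls genes with low values toward no change, so -0.13 understates the shift of well expressed genes. Turns and added lower genes under these settings need therefore not be particular to those genes. The cause of these changes was not otherwise tested. At this depth a log2 change of 1 was recovered in 78 of 100 simulated genes and of 2 in 97 of 100, with 7 other genes called. Of simulated gene lists 4 of 4 were recovered, and 1 list without a simulated change was called. The single genes given a change were drawn only from those with high mean counts. Genes were simulated independently, with the same spread in both groups and no added loss of molecules in RSL3. The recovery therefore does not carry over to low counts or to the zeros of the RSL3 libraries.

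No pairing of the libraries by replicate number was visible: across genes, deviations from the group means correlated at -0.02, -0.03 and 0.00 between libraries of the same number, and RSL3 replicate 1 correlated best with LA replicate 2 (0.05). Whether libraries of the same number share a culture is not settled by this. With a replicate block 5166 genes changed and 9 lists were shifted, without DNA damage signalling (adjusted p = 0.0508). Camera's direction for endoplasmic reticulum chaperones (-0.059) and apoptosis (-0.17) turned with the block. EMCN, VWF and RBFOX3, at 0 in RSL3, did not pass with it.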

Other observations

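The Gene Ontology terms were tested, and the genes at 0 in RSL3 singled out, after the data were seen. The tests of protrusion-localised, nuclear-retained and leukocyte transcripts were chosen after RAB13, NET1, NEAT1, MALAT1 and the immune transcripts at 0 had been seen, on other members whose values had not. The count over other splits was planned before.

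Beyond the fixed lists, Gene Ontology terms placed mitochondrial translation and the proteasome with the higher groups. Of 93 mitochondrial translation genes 50 rose and 5 fell (median log2 0.47, or 0.36 with the median transcript offsets, camera adjusted p = 2.27e-11), and of 52 proteasome complex genes 37 rose and 5 fell (0.49, or 0.26 with the offsets, camera adjusted p = 4.22e-09). With an estimated correlation neither these terms nor any other passed (smallest camera adjusted p = 0.488), although 211 terms had an unadjusted p under 0.05. Of 87 structural constituents of the extracellular matrix 38 fell and 3 rose (-1.06, or -0.53 with the offsets, camera adjusted p = 1.20e-05), and of 24 T cell activation genes 12 fell and 1 rose (-1.76, or -1.42 with the offsets, camera adjusted p = 0.00105). Any member at 0 in all RSL3 libraries enters a term with its fitted fold. The numbers that fell can therefore include zeros that do not show a fall. For the terms, the medians were not repeated with such genes taken as unchanged. In total 149 of 2235 terms were shifted upward and 46 downward, of which 110 and 10 were also shifted the same way with both length and GC offsets.

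Of the tested genes, 1102 were at 0 in all RSL3 libraries, and 12 of these had a mean of at least 500 counts in LA. Several are known from immune and mast cells: GZMB, GNLY (13.3 ± 1.47 CPM in LA), CPA3 (11.6 ± 0.672), IL2RA (11.5 ± 0.772), HDC (9.25 ± 0.432), IFNG (9.06 ± 0.442), TPSB2 (9.05 ± 0.357), IL3 (7.23 ± 0.457), BTK (6.85 ± 0.779) and PTPN6 (6.55 ± 0.391). The others were DCN (11.01 ± 2.27) and CDRT4 (8.66 ± 1.36), and unchanged levels of the 12 would give an estimated 20.4 to 63.5 distinct molecules each over the RSL3 libraries. RNA of blood cells in the LA libraries could be a source. Over 28 abundant leukocyte transcripts the median of LA minus RSL3 was 1.80 CPM, between the 5 CPM set in advance as the least that this source needs and the 1 CPM under which it would be excluded, so the test left it open. Of 27 tested, 16 passed as lower and 4 rose. Those lower include LTB, HLA-DRA, CD52 and TYROBP, at 0.688, 0.581, 0.577 and 0.423 CPM in LA and at 0 in RSL3. For these fewer than 3 distinct molecules would be expected, so their zeros do not show a fall. The most abundant moved apart: LCP1 was at 519 ± 19.9 CPM in RSL3 and 1101 ± 11.5 in LA, and SRGN at 353 ± 17.2 and 162 ± 6.76.

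RAB13 and NET1 (log2 3.30) encode transcripts known to localise to cell protrusions through the APC protein. A candidate explanation for their rise is that such transcripts rose as a group. The 7 other members had a median log2 fold change of 1.40 (camera p = 0.00194, or p = 0.0835 with an estimated correlation): TRAK2 (2.47), KIF1C (1.71), DYNLL1 (1.63), KANK2 (1.40) and PKP4 (0.90) rose, and DDR2 (-0.47) and CYB5R3 (-0.53) fell. NEAT1 (log2 -2.11) and MALAT1 (-1.74) were lower, and a fall of nuclear-retained long RNAs as a group was tested on 8 others. Their median was 0.17 (SD 0.44), with JPX higher and TUG1 lower, above the fall of MALAT1 by more than their spread, which argues against a common fall. The bound written before the result asked only for a median at or above that of all genes, and the comparison with MALAT1 was added once the median was known.

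The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, gave 7144 changed genes or more, and the highest of the others gave 0 by edgeR (54 to 107 genes at an unadjusted p under 0.05). For lists, 1 of the 10 splits gave 10 shifted lists or more, and the highest of the others gave 7. Each of the other splits gave at least 4 shifted lists with 0 changed genes. Both sides of such a split hold libraries of both groups. Part of the real difference stays in it, and the rest widens the spread within each side. These splits are therefore no null, and their 0 changed genes do not measure chance. They cannot show whether the preset correlation of 0.01 calls lists falsely.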
